A study of Homo sapiens with 20 samples.

How the data were processed

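Gene expression was measured in 20 cultures of 2 related human mammary epithelial lines with Affymetrix Human Gene 1.0 ST arrays, on which biotin-labelled copies of total RNA bind probes spread along each transcript. MCF10A is a non-tumorigenic line derived from human breast epithelium. MCF10A-HER2, written MCF10A-HER2(+) in the array titles, is its derivative that overexpresses HER2, the receptor tyrosine kinase encoded by ERBB2. Cells were grown on Matrigel, a reconstituted basement membrane, in a medium with horse serum, insulin, cholera toxin and hydrocortisone, either without epidermal growth factor (EGF) or with 20 ng/ml of it. RNA was isolated with a Versagene kit at days 1.5, 3, 5, 7 and 9. This gave 4 groups of 5 arrays, with 1 array per group and day. The array codes in the labels run in day order, so drift with array order cannot be told from day.

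The deposited values are log2 intensities that the authors made with RMA, a method that corrects background, normalises between arrays and summarises the probes of each probe set. The version of RMA, and whether all 20 arrays were processed together, are not given in the sources used here. The table held 33297 probe sets with values from 0.39 to 13.25. Of these, 19460 carried 1 gene symbol, 1754 carried several and 12083 carried none. Genes were represented by probe sets with exactly 1 symbol, and by the probe set with the highest mean over the 20 arrays where a gene had more than 1, as 769 genes did. This left 18417 genes, with no filter on level. No detection calls were among the values used, so genes with a group mean under 2.39, the median of the probe sets without a symbol, are given by their means and not by a difference. Of the probe sets with 1 symbol 19429 were matched to a human gene annotation by Entrez identifier, which supplied current names and the order of genes along chromosomes.

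Groups were compared with limma 3.58.1 in R 4.3.3. A linear model with the 4 groups and day as a block was fitted to all 20 arrays, with 12 residual degrees of freedom, so that the groups shared 1 estimate of the spread. It gave 6 comparisons, namely the EGF effect in each line, the HER2 effect without and with EGF, their interaction, and MCF10A-HER2 without EGF against MCF10A with EGF. A second model with an intercept and a linear slope on day for each group gave 7 slope results in log2 per day. Moderated tests were two-sided. Their p-values were adjusted with the Benjamini-Hochberg method over all genes of a comparison, and an adjusted p under 0.05 was called. For ERBB2 and EGFR the differences within each day were also tested with an exact sign-flip permutation test, two-sided. Its smallest possible p with 5 pairs is 0.062.

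The model, the comparisons, the alternatives, the rule for named genes and 23 gene lists were fixed before the data were examined. Named genes were ERBB2 and EGFR, up to 10 higher and 10 lower genes of each group comparison with the largest change among those called with the same sign at all 5 days, up to 6 rising and 6 falling genes of each slope, and up to 4 members of each list with the smallest adjusted p in the comparison described. Genes named outside this rule are said to be so. Lists came from textbook knowledge. They covered MAPK early response and feedback, EGF family ligands and receptors, DNA replication, mitosis, cell cycle inhibition and quiescence, the BCL2 family, the Notch pathway, basal and myoepithelial markers, hemidesmosome and basement membrane, luminal markers, squamous differentiation, mesenchymal and EMT markers, extracellular proteases and their inhibitors, interferon-stimulated genes, NF-kB and inflammatory genes, cholesterol synthesis, hypoxia and glycolysis, the unfolded protein and amino acid response, NRF2 antioxidant genes, ribosome biogenesis and MYC targets, YAP and TGF-beta targets, oxidative phosphorylation, and markers of leukocytes, endothelium, fibroblasts and adipocytes. In all 405 of the 433 listed genes were used. The symbol LOR was left out because it is an older name of more than 1 gene, LORICRIN and LOXL2. Each list was tested against all other genes with camera from limma at a preset correlation of 0.01, with the correlation estimated from the data as the alternative, and adjusted over the 23 lists of a comparison. Counts of called members are given over all genes tested and adjusted over the list alone.

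The correlation expected between effects that share control arrays was simulated. Runs of 25 neighbouring protein-coding genes with a mean log2 value of at least 5 were placed along each chromosome, and a run was called when its median change lay outside those of 1000 random sets of 25 genes drawn with a fixed seed. The runs were defined without the library labelled MCF10A without EGF at day 3. A composition index for each array was the median deviation of expressed genes on chromosomes 16, 17, 19 and 22, which are rich in GC, minus that on chromosomes 4, 6, 18 and X. Counts of called genes were compared with those of 100 splits of the arrays, the real one included. The pipeline was tested on simulated data with genes changed 1.5-, 2- and 4-fold. It recovered 34.3% to 47.8%, 67.2% to 88.1% and 92.4% to 98.5% of them in the 5 comparisons of groups, and 7.5%, 52.2% and 86.4% in the interaction. Slopes of 0.1, 0.3 and 0.6 log2 per day were recovered in 9%, 85.1% and 98.5% of genes. Among unchanged genes 4 to 12 were called in each result, the most for HER2 against EGF. Of 23 simulated lists the 1 that was shifted was called and 0 others, and all 3 lowered runs were called and 0 others. Genes were drawn independently in these simulations, with no effect of day. They therefore cannot show how often lists or runs are called falsely where genes are correlated.

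Alternatives were the mean of a gene's probe sets, every probe set as its own feature, the dimmer 50% of genes left out, a second quantile normalisation, centring each array on its median, limma with a trend and robust variance, each array and each day left out, day left out of the model or taken as a random block, only the groups compared, a 1.5-fold minimum, day as its rank or as log2, and 4 other settings of camera. Fits without the library labelled MCF10A without EGF at day 3 for the lists and the overlap, fits without the 4 arrays highest on the second principal component, with and without that library, and fits with the composition index as a covariate were chosen after seeing the data. So were the ERBB2 level with each day left out and the overlap with each array left out. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.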

Results

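Gene expression was followed over 9 days in MCF10A and MCF10A-HER2 cells growing on Matrigel, each without EGF and with 20 ng/ml EGF. The labels give the purpose as the effect of EGF and of HER2 on growth of these cells on extracellular matrix. Each of the 4 groups held 5 arrays, 1 each at days 1.5, 3, 5, 7 and 9. Days stood in for replicates, so the p-values measure only the spread between these samples. Median log2 values lay between 3.54 and 3.68 in 19 arrays and at 3.91 in MCF10A with EGF at day 5. Correlations between arrays ranged from 0.874 to 0.992, and the first principal component held 35.8% of the variance. The number of arrays limits the precision of every value.

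ERBB2, on chromosome 17 and read by probe set 8006906, was the overexpressed gene. Its mean log2 value was 11.60 ± 0.26 (SD, n = 5) in MCF10A-HER2 without EGF and 11.79 ± 0.19 with EGF. In MCF10A it was 8.08 ± 1.94 without EGF and 5.81 ± 0.12 with EGF. The difference between lines was 5.98 ± 0.23 with EGF (63-fold, SD of 5 day pairs) and 3.52 ± 1.93 without EGF (11.4-fold), higher at 5 of 5 days in both (exact permutation p = 0.062 each, the smallest possible). The library labelled MCF10A without EGF at day 3 stood apart, with an ERBB2 value of 11.35 against 6.27 to 7.96 in the other 4 of its group. Without day 3 the difference without EGF was 4.34 ± 0.67 (20.3-fold, n = 4, exact permutation p = 0.125, the smallest possible). KRT1, a keratin of differentiating epidermis read by probe set 7963491 on chromosome 12, was 3.68 in that library, 11.37 to 12.03 in the other 4 and 3.35 to 4.46 in the 10 arrays of MCF10A-HER2. Counts of genes over a whole comparison are therefore given with all 20 arrays and without this library, and list counts and gene values also without it where it moved them by more than 1.5 times.

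EGFR, the receptor that binds EGF, is on chromosome 7 and was read by probe set 8132860. Its mean log2 value was 6.72 ± 0.52 (SD, n = 5) in MCF10A without EGF, 7.64 ± 0.40 in MCF10A with EGF, 7.90 ± 0.60 in MCF10A-HER2 without EGF and 8.30 ± 0.52 in MCF10A-HER2 with EGF. It was higher with EGF in MCF10A by 0.92 ± 0.24, and in MCF10A-HER2 by 1.17 ± 0.23 without EGF and by 0.66 ± 0.73 with EGF, at 5 of 5 days each (exact permutation p = 0.062 each). In MCF10A-HER2 the EGF difference of 0.41 ± 0.74, higher at 4 of 5 days, was within the spread (exact permutation p = 0.3125). Past the limma threshold were the EGF effect in MCF10A (adjusted p = 0.0302) and the HER2 effect without EGF (adjusted p = 0.018).

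**Figure D1:**
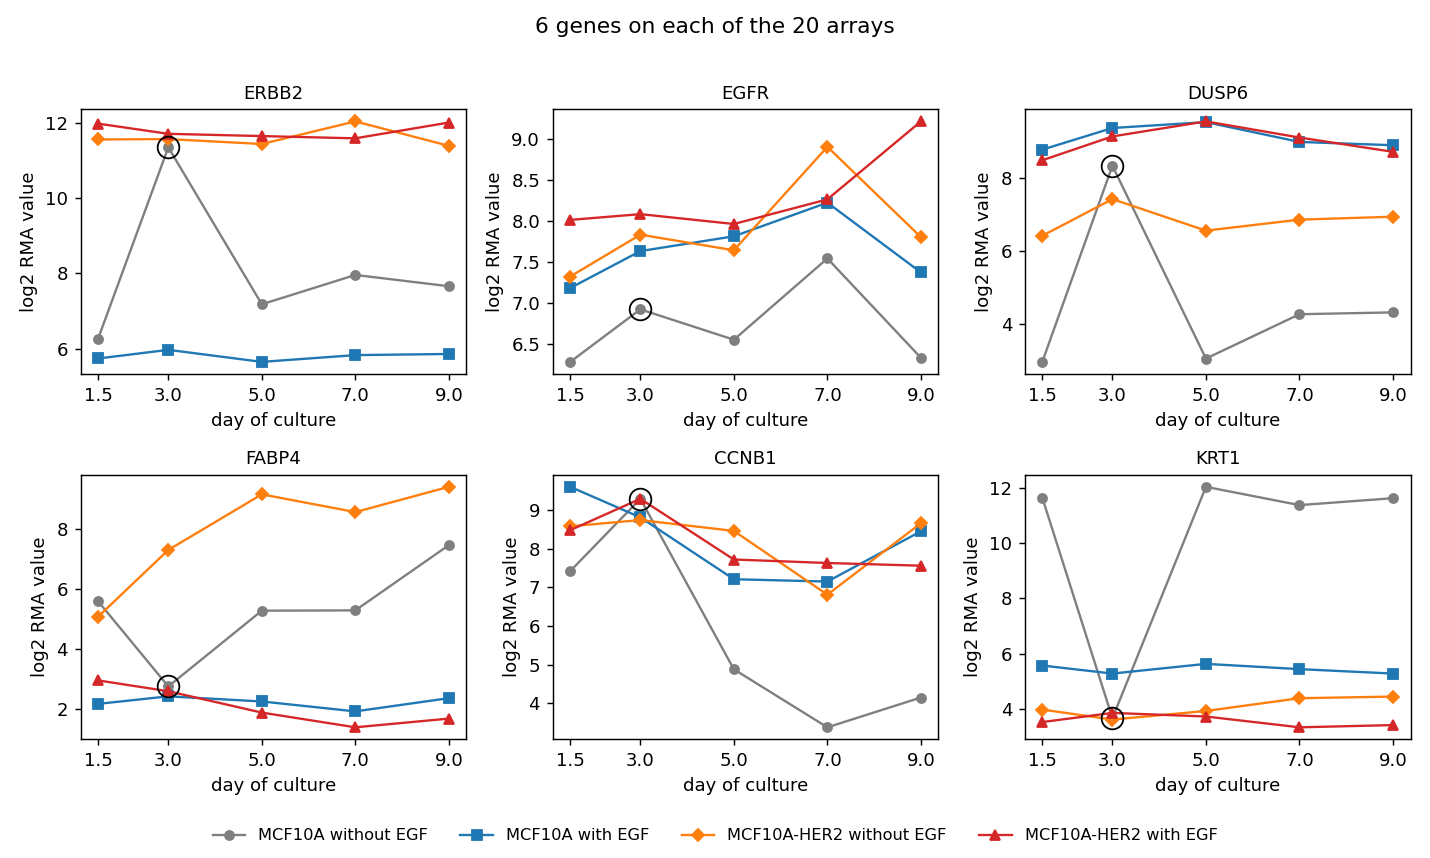
Log2 RMA values of ERBB2, EGFR, DUSP6, FABP4, CCNB1 and KRT1 (vertical axes) by day in culture (horizontal axes), with 1 point per array, 1 line per group and a black ring on the library labelled MCF10A without EGF at day 3. In that library ERBB2 is at 11.35 and KRT1 at 3.68, beside 11.39 to 12.04 and 3.35 to 4.46 in the 10 arrays of MCF10A-HER2.

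The comparison of MCF10A-HER2 with MCF10A, both without EGF, is called the HER2 effect without EGF. Every HER2 effect given here is a difference between 2 lines. HER2 cannot be told apart in it from other differences between them, such as the shifts of neighbouring genes given below. List members were placed in these runs only where they were also among the genes with the largest changes. Squamous genes were split by chromosome. Changes of other list members may share in such shifts. KRT1 fell by 5.98 ± 0.99 on the log2 scale (SE, n = 5 per group, 63.3-fold, adjusted p = 0.00978), from a mean of 10.07 to 4.08, with values from 11.37 to 12.03 in MCF10A except in the library labelled MCF10A without EGF at day 3 (3.68). CDSN, which encodes a corneodesmosome protein, had a log2 change of -3.57 ± 0.86 (adjusted p = 0.0393), and LCE3D, a late cornified envelope gene, one of -3.56 ± 0.65 (adjusted p = 0.0133). KLK7, SPRR2E and SPRR2A had log2 changes of -2.70, -2.28 and -2.03, and CES1, GDA and SDR16C5 of -2.37, -2.31 and -2.06. RPTN went from a mean of 4.31 (4.90 without that library) to 1.86. Higher besides ERBB2 were OLFM4, a secreted glycoprotein (2.68 ± 0.39, 6.41-fold, adjusted p = 0.00498), the cytokine gene IL1A (2.48 ± 0.40), the lysyl oxidase gene LOXL2 (2.36), SNORD116-21 (2.46), ZNF626 (2.18), LGALS3BP (2.15), ADSS1 (2.11), PXDN (2.07) and FCRLA (2.04). Within runs of neighbouring genes that were lower together in this line lie LCE3D, RPTN, SPRR2A, SPRR2E and FCRLA on chromosome 1 and OLFM4 on chromosome 13, of which FCRLA and OLFM4 went against their runs. With that library left out the changes were -7.55 for KRT1, -4.48 for CDSN, -3.37 for KLK7, 3.09 for IL1A and 4.33 for ERBB2. The rule for named genes required 1 direction at all 5 days, and the smallest daily change was -0.05 for KRT1 and -0.07 for CDSN.

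Among the lists for HER2 without EGF, 11 of 25 mitosis genes were higher and 24 when adjusted over the list alone, with PLK1 at 2.82 ± 0.56, TPX2 at 2.37 ± 0.51 and TOP2A at 2.16 ± 0.46 (camera adjusted p = 1.38e-22, adjusted p = 0.315 with an estimated correlation). Of 25 DNA replication genes 3 were higher, CDT1 (1.67), MCM2 (1.40) and RRM2 (2.16), and 16 when adjusted over the list alone (camera adjusted p = 1.25e-13, adjusted p = 0.315 with an estimated correlation). These 2 counts were 25 and 24 over all genes without the library labelled MCF10A without EGF at day 3, with PLK1 at 3.49, TPX2 at 3.06 and RRM2 at 2.92. Of 21 MAPK early response genes 2 were higher, MYC (1.04 ± 0.20) and DUSP6 (2.24 ± 0.58, a phosphatase induced by ERK signalling), and 6 when adjusted over the list alone against 1 lower (camera adjusted p = 0.00156, adjusted p = 0.438 with an estimated correlation). Hypoxia and glycolysis genes had 2 higher, BNIP3 (0.90) and PDK1 (1.05), and 4 when adjusted over the list alone (camera adjusted p = 7.36e-06, adjusted p = 0.347 with an estimated correlation). Ribosome biogenesis genes had 2 higher, BOP1 (1.02) and FBL (1.12), and 2 when adjusted over the list alone (camera adjusted p = 7.88e-06, adjusted p = 0.438 with an estimated correlation). NF-kB genes had 2 higher, IL1A and C3 (0.87), and 4 when adjusted over the list alone (camera adjusted p = 0.0264, adjusted p = 0.315 with an estimated correlation). Hemidesmosome genes had ITGA3 (1.10) and ITGB4 (1.31) higher and NID1 (mean 3.38 to 2.20) lower, with 7 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.315 with an estimated correlation). AMOTL2 (0.73) was the called member of 15 YAP and TGF-beta targets, with 4 when adjusted over the list alone (camera adjusted p = 0.0146, adjusted p = 0.315 with an estimated correlation). With that library left out, called members were 7 higher and 1 lower for MAPK (DUSP6 at 3.09), 6 for hypoxia, and 9 for ribosome biogenesis. They were 6 higher and 1 lower for NF-kB (IL1A at 3.09), 2 higher and 3 lower for hemidesmosome and 2 for YAP genes. The hemidesmosome and YAP lists then no longer passed (camera adjusted p = 0.146 each).

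Of 23 squamous differentiation genes measured in MCF10A-HER2 without EGF, KRT1 and SERPINB4 (-1.60) were lower and CSTA (0.80) was higher, with 6 lower and 1 higher when adjusted over the list alone (camera adjusted p = 1.07e-05, adjusted p = 0.438 with an estimated correlation). Of these genes 14 were lower and 1 higher without the library labelled MCF10A without EGF at day 3. The 8 members on chromosome 1, where neighbouring genes were lower together in this line, had a median log2 change of -1.26 and the 15 on other chromosomes one of -0.92, or -1.92 and -1.53 without that library. NRF2 antioxidant genes had AKR1B10 (-2.67) lower, and 5 of 14 when adjusted over the list alone (camera adjusted p = 7.88e-06, adjusted p = 0.315 with an estimated correlation). Quiescence genes had 0 of 16 called, and 0 when adjusted over the list alone, with a list median of -0.26 (camera adjusted p = 0.0418, adjusted p = 0.606 with an estimated correlation). The pro-apoptotic genes BMF (-0.85) and BCL2L11 (-0.70) were lower and BID (1.04) was higher within the BCL2 family, in which 2 were lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.993, with a median of 0.002 and a mean of -0.01). Among markers of other cell types KDR, an endothelial receptor gene, was lower (-0.88), the called member of 17 in a list that did not pass (camera adjusted p = 0.239). With that library left out 6 NRF2 genes (AKR1B10 at -3.66) and 7 quiescence genes were lower, 2 BCL2 family genes were higher, markers of other cell types had 1 higher and 2 lower, and KRT1 was at -7.55.

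With all arrays limma called 522 genes for HER2 without EGF, 277 higher and 245 lower, of which 357 had 1 sign at all 5 days (68.4%). For 5 independent random signs that share would be 6.25%, a calculated value, and choosing genes by the test itself favours 1 sign. Without the library labelled MCF10A without EGF at day 3 it called 2758, 1478 higher and 1280 lower, among them all 522. Leaving out 1 array gave 97 to 276 genes without MCF10A without EGF at day 1.5, 5, 7 or 9, 116 to 191 without MCF10A-HER2 without EGF at day 1.5, 5, 7 or 9, and 346 without MCF10A with EGF at day 7. Leaving out a whole day gave 19 (day 1.5), 2096 (day 3), 1 (day 5), 1 (day 7) and 2 (day 9).

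**Figure D2:**
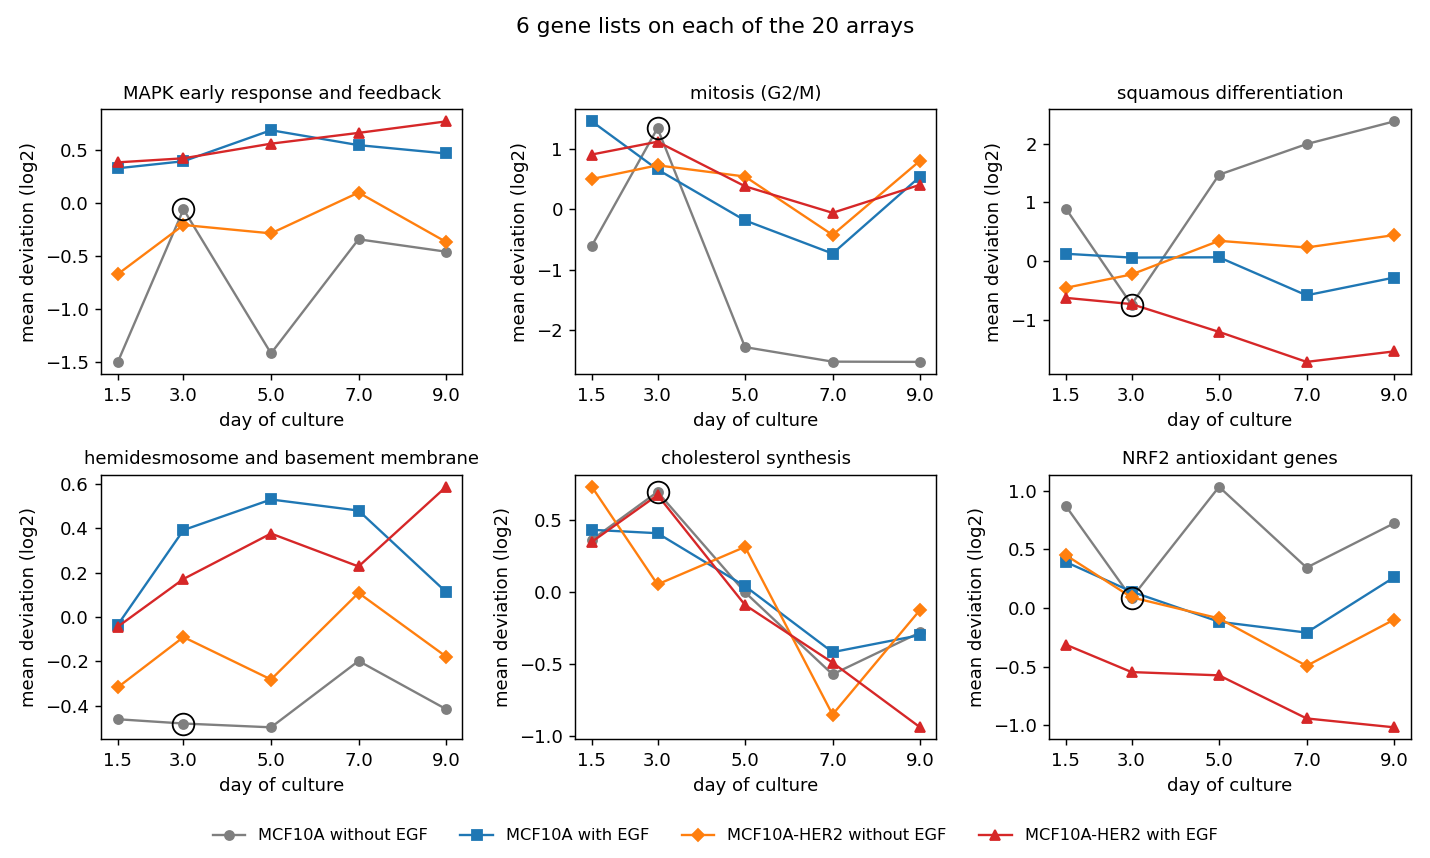
Mean deviation of a list's genes from their mean over the 20 arrays (vertical axes, log2) by day in culture (horizontal axes) for 6 lists, with 1 point per array, 1 line per group and a black ring on the library labelled MCF10A without EGF at day 3. The lists are MAPK response, mitosis, squamous differentiation, hemidesmosome, cholesterol synthesis and NRF2 genes. In that library mitosis genes are at 1.34, against -2.52 to -0.60 in the other 4 arrays of its group, and squamous genes at -0.73, against 0.90 to 2.38.

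The 2 lines were also compared with EGF, and the HER2 effect is again a difference between lines. DCN, which encodes the matrix proteoglycan decorin and served as a fibroblast marker, fell by 4.32 ± 0.76 in MCF10A-HER2 (SE, n = 5 per group, 20-fold, adjusted p = 0.00579), from a mean log2 value of 8.01 in MCF10A. TFPI2, a serine protease inhibitor gene, had a log2 change of -3.37 ± 0.36 (adjusted p = 0.000286), IL1R2, the decoy receptor for interleukin 1, one of -2.55 ± 0.23 (adjusted p = 7.71e-05) and KRT14, a basal keratin, one of -2.59 ± 0.32 (adjusted p = 0.000599). RRAD (-3.08), CES1 (-2.95), CCNA1 (-2.77) and CYB5R2 (-2.71) were also lower. So were CLIC2 (mean 5.77 to 1.94) and AKR1B10 (5.34 to 2.09). Higher besides ERBB2 were FSTL1, a secreted glycoprotein (3.05 ± 0.46, 8.31-fold, adjusted p = 0.00208), ZNF626 (2.75), the amino acid transporter gene SLC6A14 (2.29), LGALS3BP (2.12), FNDC3B (2.10), TM4SF1 (2.04), BLMH (1.95), ALOX5AP (1.93) and IL1RAP (1.85). Of these FSTL1, FNDC3B, TM4SF1 and IL1RAP lie on chromosome 3 within runs of neighbouring genes that were higher together in this line, and CCNA1 and ALOX5AP on chromosome 13 within runs that were lower, against which ALOX5AP went. All named genes had 1 direction at all 5 days, by rule.

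NRF2 antioxidant genes were lower in MCF10A-HER2 with EGF in 5 of 14 measured and in 6 when adjusted over the list alone (camera adjusted p = 4.73e-06, adjusted p = 0.321 with an estimated correlation). They included AKR1C3 (-1.31), AKR1C2 (-1.10) and NQO1 (-1.19), which encode enzymes that reduce carbonyls and quinones. Squamous genes were lower in 3 of 23, KRT10 (-2.33), S100A8 (-2.12) and SPRR1B (-1.42), and in 8 when adjusted over the list alone (camera adjusted p = 1.46e-05, adjusted p = 0.6 with an estimated correlation). Their median change was -1.57 for the 8 members on chromosome 1 and -0.46 for the other 15. The unfolded protein response had 0 of 17 called and 4 higher when adjusted over the list alone (camera adjusted p = 0.00219, adjusted p = 0.6 with an estimated correlation). Oxidative phosphorylation genes had 0 of 17 called and 1 lower when adjusted over the list alone (camera adjusted p = 0.00714, adjusted p = 0.6 with an estimated correlation). Mitosis genes had 0 of 25 called, over all genes or over the list alone (median 0.19, camera adjusted p = 0.195). Basal markers had KRT14 and SFN (-0.66) lower, while the list was not shifted (camera adjusted p = 0.887, median 0.01, mean -0.12). The luminal keratin KRT8 was higher (1.59 ± 0.17), in a list that did not pass (camera adjusted p = 0.343). Of 18 mesenchymal markers S100A4 was lower (-2.32 ± 0.30) and MMP2 (0.96) higher, with 2 higher and 1 lower when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.376). The protease genes MMP14 (0.86), MMP2 and PLAU (1.39) were the called members of 16 (camera adjusted p = 0.0859), and DCN and the monocyte marker CD14 (-1.09) those of 17 markers of other cell types (camera adjusted p = 0.268). In a fit without the library labelled MCF10A without EGF at day 3 7 squamous genes were lower, 4 genes of the unfolded protein response were higher and 1 of oxidative phosphorylation was lower. The mitosis list then passed with 0 genes called (camera adjusted p = 0.0429, adjusted p = 0.751 with an estimated correlation). So did DNA replication genes, with 2 of 25 higher over all genes and over the list alone (camera adjusted p = 0.00449, adjusted p = 0.676 with an estimated correlation), and EGF family genes, with 1 of 12 higher and 3 when adjusted over the list alone (camera adjusted p = 0.031, adjusted p = 0.676 with an estimated correlation). The 1 EGF family gene called was ERBB2 (5.98), the gene this line overexpresses, and the list was not tested without it.

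For HER2 with EGF limma called 539 genes, 168 higher and 371 lower, of which 532 had 1 sign at all 5 days (98.7%). Without the library labelled MCF10A without EGF at day 3, which enters this comparison through the shared spread and the day block, it called 924, 322 higher and 602 lower. Leaving out 1 array gave 282 to 316 genes without MCF10A with EGF at day 1.5, 3, 7 or 9, and 265 to 311 without MCF10A-HER2 with EGF at day 1.5, 5 or 9, and leaving out day 1.5, 5 or 9 gave 152, 217 or 156. Centring each array on its median gave 199 higher and 259 lower.

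**Figure D3:**
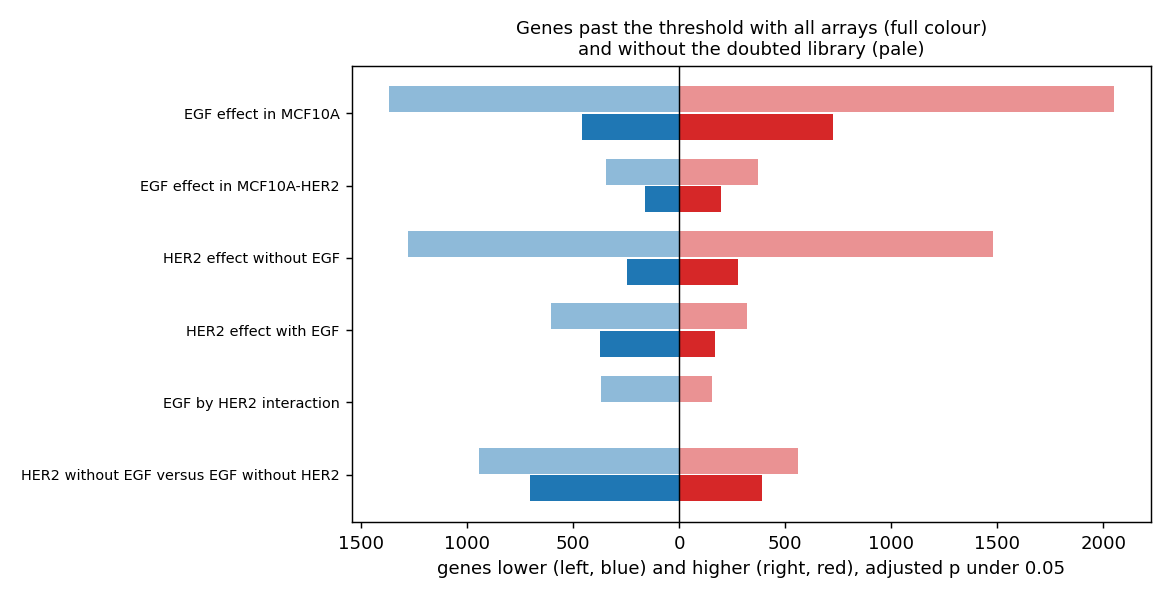
Genes with an adjusted p under 0.05 in limma (horizontal axis, lower to the left in blue and higher to the right in red) for each group comparison (vertical axis), with all 20 arrays in full colour and without the library labelled MCF10A without EGF at day 3 in pale. The interaction went from 2 to 525 genes and the EGF effect in MCF10A from 1183 to 3421.

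The effect of EGF in MCF10A was read from its arrays with and without the growth factor. DUSP6, a phosphatase that feeds back on ERK, rose by 4.51 ± 0.58 on the log2 scale (SE, n = 5 per group, 22.7-fold, adjusted p = 0.00039). NT5E, which encodes the ectonucleotidase CD73, rose by 4.45 ± 0.71 (adjusted p = 0.00179), the protease inhibitor gene SERPINE2 by 3.94 ± 0.41 (adjusted p = 7.9e-05), and the chemokine gene CCL20 by 3.54 ± 0.54 (adjusted p = 0.00136). EMP3 (3.54), PLEK2 (3.08), IL1A (2.99) and PKP2 (2.95) also rose. So did TFPI2 (mean 2.36 to 6.28, adjusted p = 5.53e-05) and MIR4697HG (2.30 to 5.30). KRT4, a keratin of stratified mucosa, fell by 4.30 ± 0.85 (19.6-fold, adjusted p = 0.0071). FABP4, a fatty acid binding protein gene used as an adipocyte marker and read by probe set 8151532 on chromosome 8, fell from a mean of 5.28 to 2.23 (adjusted p = 0.0202). HSD11B2 (-3.04), CCDC80 (-2.49), GBP2 (-2.45), CYFIP2 (-2.43), ADGRL2 (-2.42), GPX2 (-2.39), ERBB2 (-2.27) and PRICKLE1 (-2.23) were lower too. Leaving out the library labelled MCF10A without EGF at day 3 gave FABP4 a mean of 5.90 without EGF. Changes were then 5.36 for DUSP6, 5.47 for NT5E, 4.21 for CCL20, 4.21 for EMP3, 3.82 for PLEK2, 3.60 for IL1A, -5.24 for KRT4, -3.73 for HSD11B2, -3.08 for GBP2 and -1.46 for ERBB2. Each gene here had 1 direction at all 5 days, by rule.

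With EGF in MCF10A, MAPK early response genes were higher in 10 of 21, and in 13 when adjusted over the list alone, with SPRY2 at 2.81 ± 0.31, SPRY4 at 2.20 ± 0.24 and ETV4 at 2.04 ± 0.31 (camera adjusted p = 3.38e-12, adjusted p = 0.133 with an estimated correlation). Mitosis genes were higher in 13 of 25, and in 25 when adjusted over the list alone, with PLK1 at 2.45 ± 0.56, CENPF at 2.13 and KIF20A at 2.06 (camera adjusted p = 2.42e-15, adjusted p = 0.225 with an estimated correlation). DNA replication genes had 1 of 25 called, CDT1 (1.44), and 1 when adjusted over the list alone (camera adjusted p = 1.35e-06, adjusted p = 0.468 with an estimated correlation). Ribosome biogenesis genes had ODC1 (1.88) and FBL (1.01) higher, and 9 of 16 when adjusted over the list alone (camera adjusted p = 5.46e-06, adjusted p = 0.34 with an estimated correlation). Of 18 hypoxia and glycolysis genes BNIP3 (0.82) was higher, and 5 when adjusted over the list alone (camera adjusted p = 0.00143, adjusted p = 0.469 with an estimated correlation). Among EGF family genes EREG (0.86), ERRFI1 (1.37, a feedback inhibitor of EGFR) and EGFR were higher, and 2 of 12 were lower, with 4 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.491). Of 14 BCL2 family genes MCL1 (1.12) and BCL2L1 (0.58) were higher and BCL2L11 (-0.86) and BMF (-0.79) lower, with 10 not past the threshold, the same counts when adjusted over the list alone, and a list that did not pass (median -0.05, camera adjusted p = 0.491). Called members over all genes without the library labelled MCF10A without EGF at day 3 were 25 for mitosis (PLK1 at 3.12), 23 for DNA replication, 12 for ribosome biogenesis and 5 for hypoxia genes. Quiescence genes, with 1 of 16 lower in the fit of all arrays (camera adjusted p = 0.154), then had 3 lower, 9 lower and 1 higher when adjusted over the list alone, and passed (camera adjusted p = 0.00193, adjusted p = 0.254 with an estimated correlation).

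Of 14 hemidesmosome and basement membrane genes in MCF10A, 8 were higher and 1 lower with EGF, with the same counts when adjusted over the list alone, and LAMB3 at 2.00 ± 0.20, ITGA2 at 1.96 ± 0.35 and ITGA3 at 1.17 (camera adjusted p = 5.46e-06, adjusted p = 0.133 with an estimated correlation). NF-kB genes were higher in 6 of 19, over all genes and over the list alone, with IL1R2 at 2.94 ± 0.23 and PTGS2 at 1.70 ± 0.21 (camera adjusted p = 0.00143, adjusted p = 0.133 with an estimated correlation). Proteases and their inhibitors were higher in 4 of 16, TIMP1 (2.28), PLAT (1.24), PLAU (1.29) and CTSL (0.86), and in 6 when adjusted over the list alone (camera adjusted p = 0.00376, adjusted p = 0.235 with an estimated correlation). Mesenchymal markers had 4 of 18 higher over all genes and over the list alone, FN1 (2.02), S100A4 (1.41), VIM (1.36) and SNAI2 (1.15), while the list did not pass (camera adjusted p = 0.154). NF-kB genes without the library labelled MCF10A without EGF at day 3 had 7 higher and 2 lower, 9 and 2 when adjusted over the list alone, and passed with an estimated correlation too (camera adjusted p = 0.000489, adjusted p = 0.0391 with an estimated correlation). Without it mesenchymal markers had 4 higher and 1 lower.

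Squamous genes were lower with EGF in MCF10A in 6 of 23, and in 14 when adjusted over the list alone, with 1 higher, KRT1 at -4.62 ± 0.99, DSG1 at -2.01 ± 0.46, KRT10 at -2.20 and KRT16 at -1.61 (camera adjusted p = 3.37e-09, adjusted p = 0.235 with an estimated correlation). Luminal markers were lower in 6 of 21 and in 7 when adjusted over the list alone, with 1 higher, and KRT8 at -1.10 ± 0.17, GATA3 at -1.35 and ELF3 at -2.25 (camera adjusted p = 0.00573, adjusted p = 0.225 with an estimated correlation). NRF2 genes were lower in 3 of 14, GCLM (-0.88), TXNRD1 (-1.51) and HMOX1 (-0.79), and in 6 when adjusted over the list alone (camera adjusted p = 6.32e-05, adjusted p = 0.164 with an estimated correlation). Interferon-stimulated genes were lower in 4 of 22, with RIGI at -0.86, OAS1 at -0.72 and ISG15 at -0.42, and in 6 when adjusted over the list alone (camera adjusted p = 0.00142, adjusted p = 0.133 with an estimated correlation). Of 17 markers of other cell types FABP4 was called, with 2 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.936). With the library labelled MCF10A without EGF at day 3 left out, called members over all genes were 15 lower and 1 higher for squamous genes (KRT1 at -6.19, KRT10 at -2.80), and 7 lower and 2 higher for luminal markers (ELF3 at -2.88). They were 7 lower for NRF2 genes, 4 lower and 2 higher for interferon genes and 3 lower and 2 higher for markers of other cell types (FABP4 at a mean of 5.90 without EGF and 2.23 with it).

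For EGF in MCF10A limma called 1183 genes, 725 higher and 458 lower, of which 825 had 1 sign at all 5 days (69.7%). Without the library labelled MCF10A without EGF at day 3 it called 3421, 2051 higher and 1370 lower, with 1173 genes in both. Leaving out 1 array gave 604 to 659 genes without MCF10A without EGF at day 5, 7 or 9, and 661 to 731 without MCF10A with EGF at day 1.5, 5, 7 or 9, and leaving out days 1.5, 3, 5, 7 and 9 gave 546, 2849, 231, 514 and 402. A second quantile normalisation gave 571 higher and 657 lower.

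In MCF10A-HER2 the effect of EGF was read in the same way. FABP4 fell from a mean log2 value of 7.90 without EGF to 2.11 with it (adjusted p = 0.00106). SERPINB13 (-3.36 ± 0.53, SE, n = 5 per group, adjusted p = 0.0042), KRT10 (-3.35 ± 0.52, adjusted p = 0.00356), the gap junction gene GJA1 (-3.19), GPR15LG (-2.97), PLA2G2A (-2.66), OLFM4 (-2.52), the helix-loop-helix regulator ID2 (-2.51), AZGP1 (-2.42) and the fatty acid receptor gene CD36 (mean 4.71 to 2.21) were lower. EMP3 rose by 2.99 ± 0.56 (7.96-fold, adjusted p = 0.0118) and THBS1, which encodes the matrix protein thrombospondin, by 2.99 ± 0.71 (adjusted p = 0.0406). NT5E (2.91), SERPINE2 (2.79 ± 0.41, adjusted p = 0.00255), ANTXR2 (2.70), LTBP1 (2.43), the glucose transporter gene SLC2A3 (2.39), INHBA (2.37), the ERK target ETV5 (2.37) and PLEK2 (2.29) also rose. Each gene here had 1 direction at all 5 days, as the rule required.

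MAPK early response genes were higher with EGF in MCF10A-HER2 in 6 of 21, and in 13 when adjusted over the list alone against 1 lower, with SPRY4 at 1.52 ± 0.24, DUSP5 at 1.42 ± 0.23 and ETV4 at 1.73 (camera adjusted p = 3.09e-12, adjusted p = 0.0958 with an estimated correlation). Proteases and inhibitors had TIMP2 (0.91 ± 0.16) higher, and 7 of 16 when adjusted over the list alone (camera adjusted p = 2.47e-06, adjusted p = 0.0958 with an estimated correlation). Hemidesmosome genes had LAMB3 (0.95), ITGA2 (1.46) and COL4A2 (0.87) higher, and 5 of 14 when adjusted over the list alone (camera adjusted p = 0.000127, adjusted p = 0.105 with an estimated correlation). Mesenchymal markers had 0 of 18 called and 3 higher when adjusted over the list alone (camera adjusted p = 0.000781, adjusted p = 0.322 with an estimated correlation). The unfolded protein response had TRIB3 (0.82) higher, and 2 of 17 when adjusted over the list alone (camera adjusted p = 0.0312, adjusted p = 0.463 with an estimated correlation). NF-kB genes had CCL20 (2.24), IL1B (1.79) and CSF3 (1.14) higher and SAA1 (-1.42) lower, with 6 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.0336, adjusted p = 0.294 with an estimated correlation). Squamous genes were lower in 4 of 23, KRT10, S100A8 (-2.33), KRT16 (-1.76) and CSTA (-0.88), and in 11 when adjusted over the list alone (camera adjusted p = 5.19e-13, adjusted p = 0.198 with an estimated correlation). NRF2 genes were lower in 4 of 14, NQO1 (-1.12), PGD (-0.93), AKR1C2 (-0.97) and GCLC (-0.92), and in 7 when adjusted over the list alone (camera adjusted p = 2.06e-08, adjusted p = 0.0958 with an estimated correlation). Oxidative phosphorylation genes had 0 of 17 called, over all genes or over the list alone, and a median of -0.18 (camera adjusted p = 0.0399, adjusted p = 0.705 with an estimated correlation). Mitosis genes had 0 of 25 called, over all genes or over the list alone (median 0.15, camera adjusted p = 0.637), and DNA replication genes had 0 of 25 (median -0.02, camera adjusted p = 0.963). With the library labelled MCF10A without EGF at day 3 left out, called members over all genes were 10 for MAPK, 6 for proteases, 9 lower for squamous, 1 for mesenchymal, 2 for unfolded protein response and 5 higher and 1 lower for NF-kB genes. Oxidative phosphorylation then no longer passed (camera adjusted p = 0.0618), and NF-kB and NRF2 genes passed with an estimated correlation too (adjusted p = 0.0394 each).

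For EGF in MCF10A-HER2 limma called 356 genes, 196 higher and 160 lower, of which 345 had 1 sign at all 5 days (96.9%). Without the library labelled MCF10A without EGF at day 3, which enters through the shared spread and the day block, it called 719, 372 higher and 347 lower. Leaving out 1 array gave 131 to 237 genes without any 1 array of MCF10A-HER2 without EGF, and 143 and 122 without MCF10A-HER2 with EGF at days 5 and 9. Leaving out days 1.5, 5, 7 and 9 gave 209, 93, 203 and 80.

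Whether EGF acted differently in the 2 lines was tested by the interaction. The interaction was -2.24 ± 0.32 on the log2 scale for IL1R2 and -2.05 ± 0.29 for MYEOV (SE, adjusted p = 0.0292 each, 1 direction at 5 of 5 days), and limma called these 2 genes with all arrays, against 1439 at an unadjusted p under 0.05. IL1R2 averaged 3.43 without and 6.37 with EGF in MCF10A, and 3.12 and 3.82 in MCF10A-HER2. MYEOV averaged 4.61 without and 6.29 with EGF in MCF10A, and 5.59 and 5.21 in MCF10A-HER2, where its EGF effect of -0.38 was not past the threshold (adjusted p = 0.565). Lists passed camera as shifts of the whole list. Mitosis genes had a median interaction of -1.59, with 0 of 25 called and 11 lower when adjusted over the list alone (camera adjusted p = 3.57e-15, adjusted p = 0.536 with an estimated correlation). DNA replication genes had one of -0.87, with 0 of 25 called over all genes or over the list alone (camera adjusted p = 7.23e-07, adjusted p = 0.672 with an estimated correlation). MAPK early response genes had a median of -0.28 and 0 of 21 called (camera adjusted p = 0.0558), and squamous genes one of -0.15 with a mean of 0.09 (camera adjusted p = 0.951).

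The number of genes with an interaction rested on the library labelled MCF10A without EGF at day 3. Without it limma called 525 genes, 155 higher and 370 lower, and 23 of 25 mitosis genes, 15 of 25 DNA replication genes and 4 of 21 MAPK genes were lower, and 2 of 23 squamous genes were higher. The MAPK and squamous lists then passed (camera adjusted p = 0.0053 and 0.00953, adjusted p = 0.709 and 0.844 with an estimated correlation), as did quiescence genes with 0 of 16 called (camera adjusted p = 0.0053, adjusted p = 0.58 with an estimated correlation). In that fit KRT1 had an EGF effect in MCF10A of -6.19 and an interaction of 5.69 ± 0.25 (adjusted p = 4.54e-09). CCNB1, the mitotic cyclin B1, rose in MCF10A by 3.10 and had an interaction of -3.22 ± 0.58 (adjusted p = 0.00936). DUSP6 rose by 5.36 in MCF10A and by 2.15 in MCF10A-HER2, with an interaction of -3.21 ± 0.35 (adjusted p = 0.000374). MELK (-3.27), PBK (-3.21) and PLK1 (-2.97) were among the lower genes and PDK4 (3.13), MUC15 (2.97) and LORICRIN (2.95) among the higher. These genes were chosen after their values were seen. The 2 genes called with all arrays lost their call in most fits with 1 array or day left out, which gave 0 to 4 genes apart from that library and 236 without day 3.

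The comparison of MCF10A-HER2 without EGF with MCF10A with EGF set the HER2 line against the ligand. MCF10A without EGF entered it only through the shared spread and the day block. FABP4 was higher with HER2 (mean 7.90 against 2.23, adjusted p = 0.000228), and OLFM4 by 3.58 ± 0.39 (SE, n = 5 per group, 12-fold, adjusted p = 6.33e-05). CCDC80 (2.95), the complement gene CFB (2.89), ZNF626 (2.84), PLA2G2A (2.84), GPR15LG (2.82), CYFIP2 (2.79) and VGLL1 (2.68) were higher as well, besides ERBB2 (5.79). DCN fell by 5.11 ± 0.76 (34.4-fold, adjusted p = 0.000791), SERPINE2 by 4.05 ± 0.41 (adjusted p = 3.6e-05), and IL1R2 by 3.25 ± 0.23 (adjusted p = 8.75e-07). LCE3D (-3.58), HEPHL1 (-3.33), CYB5R2 (-3.32), CCL20 (-3.13) and EMP3 (-3.12) were lower too. So were TFPI2 (mean 6.28 to 2.29, adjusted p = 1.77e-05) and CLIC2 (5.77 to 2.25). CCDC80 on chromosome 3 and LCE3D on chromosome 1 lie within runs of genes that were higher and lower together in MCF10A-HER2. OLFM4 on chromosome 13 lies within a run that was lower, and went against it. By rule, these genes had 1 direction at all 5 days.

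MAPK feedback genes were lower with HER2 than with EGF in 6 of 21, and in 7 when adjusted over the list alone, with SPRY2 at -2.41 ± 0.31, SPRY4 at -2.34 ± 0.24, ETV4 at -1.59 and DUSP1 at -0.84 (camera adjusted p = 9.06e-06, adjusted p = 0.408 with an estimated correlation). Hemidesmosome genes were lower in 4 of 14, LAMB3 (-1.43), COL7A1 (-1.09), ITGA2 (-1.27) and COL4A1 (-0.76), and in 6 when adjusted over the list alone (camera adjusted p = 0.0179, adjusted p = 0.408 with an estimated correlation). Luminal markers were higher in 4 of 21, KRT8 (1.53 ± 0.17), CD24 (1.45), ESR1 (0.73) and FOXA1 (0.72), and in 5 when adjusted over the list alone (camera adjusted p = 0.0179, adjusted p = 0.408 with an estimated correlation). YAP and TGF-beta targets were higher in 4 of 15 over all genes and over the list alone, AMOTL2 (1.26), ID3 (1.51), CCN1 (1.24) and ID2 (1.68), of which ID2 and ID3 encode inhibitors of helix-loop-helix factors (camera adjusted p = 0.0179, adjusted p = 0.408 with an estimated correlation). In the Notch pathway the receptor NOTCH1 (1.02), the ligand JAG2 (0.98) and LFNG (0.66) were higher and the target HEY1 (-0.84) was lower, with 4 higher and 2 lower of 20 when adjusted over the list alone (camera adjusted p = 0.092). Mitosis genes had 0 of 25 called, over all genes or over the list alone (median 0.10, camera adjusted p = 0.428). Luminal markers had 5 higher and 1 lower with the library labelled MCF10A without EGF at day 3 left out. DNA replication genes then passed with 1 of 25 higher over all genes and over the list alone (camera adjusted p = 0.00977, adjusted p = 0.671 with an estimated correlation).

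For this comparison limma called 1091 genes, 390 higher and 701 lower, of which 1059 had 1 sign at all 5 days (97.1%). It called 1503, 561 higher and 942 lower, without the library labelled MCF10A without EGF at day 3. Leaving out days 1.5, 5 and 9 gave 672, 599 and 687 genes. A second quantile normalisation gave 484 higher and 576 lower.

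The effects were compared across the 18417 genes, which are not independent replicates. The 2 EGF effects, which share no array, had a Pearson r of 0.567 and a Spearman rho of 0.351, with 114 genes higher in both against 7.72 by chance, 73 lower in both against 3.98, and 0 in opposite directions. Without the library labelled MCF10A without EGF at day 3 these were 255 against 41.4 and 240 against 25.8, with 1 gene in each opposite direction. The 2 HER2 effects, which share no array either, had an r of 0.471 and a rho of 0.327, with 45 genes higher in both against 2.53 by chance and 80 lower in both against 4.94. These were 177 against 25.8 and 283 against 41.8 without that library, with 7 and 3 in opposite directions. The EGF effect in MCF10A and the HER2 effect without EGF share their control arrays. Their r was 0.59, against 0.497 in simulations with that sharing alone, and their covariance was 0.102 against 0.0222. In both effects 110 genes were higher and 69 lower, and 1025 and 757 without that library, against 10.9 and 6.09, and 165 and 95.2, for independent lists, values that leave out the shared controls. With the control arrays split between the 2 effects, r averaged 0.286 over 10 splits, from 0.0272 to 0.503. The r with shared controls was 0.75 without that library, against 0.571 simulated (covariance 0.213 against 0.0237), and 0.573 on average with controls split without day 3.

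Changes over time were read as slopes on day, which share their direction with array order. In MCF10A without EGF, CDSN rose by 0.91 ± 0.13 log2 per day (SE, 5 arrays, adjusted p = 0.00158), FLG, which encodes filaggrin, by 0.87 ± 0.11 (adjusted p = 0.000411) and LCE3D by 0.86 ± 0.09 (adjusted p = 0.000221), with SPINK7 (0.89), KRT4 (0.86) and CEL (0.83). CCNB1 fell by 0.67 ± 0.16 per day (adjusted p = 0.0343), and PBK (-0.71), SERPINA3 (-0.62), PLK1 (-0.61), TPX2 (-0.52) and ODC1 (-0.48) were also falling. Squamous genes rose in 8 of 23 and in 13 when adjusted over the list alone, SPRR3 (0.74) and IVL (0.70) among them (camera adjusted p = 1.12e-11, adjusted p = 0.309 with an estimated correlation). Mitosis genes fell in 3 of 25 over all genes and in 25 when adjusted over the list alone (camera adjusted p = 4.32e-16, adjusted p = 0.309 with an estimated correlation). Hypoxia and glycolysis genes rose in 4 of 18, HK2 (0.53), VEGFA (0.55), NDRG1 (0.41) and MXI1 (0.19), and in 6 when adjusted over the list alone (camera adjusted p = 7.94e-05, adjusted p = 0.311 with an estimated correlation). NOTCH3, on chromosome 19 and read by probe set 8034940, rose by 0.46 ± 0.11 per day (adjusted p = 0.0389), a call that ended without the library labelled MCF10A without EGF at day 3 (0.39, adjusted p = 0.12). PBK, CCNB1 and MXI1 lost their calls without it too (-0.50, -0.49 and 0.19, adjusted p = 0.111, 0.0799 and 0.0684), and 2 mitosis genes were falling, 14 when adjusted over the list alone, while hypoxia genes had 5 rising and 10 over the list alone. The macrophage marker CD68, also a lysosomal gene, rose by 0.41 ± 0.09 per day (adjusted p = 0.0192, and 0.0557 without that library).

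The other groups had fewer slopes past the threshold. In MCF10A with EGF limma called RNF175 (0.35 ± 0.04 per day, adjusted p = 0.001) and the cationic amino acid transporter gene SLC7A2 (0.32 ± 0.04, adjusted p = 0.0131). In MCF10A-HER2 with EGF the intermediate filament gene VIM (0.44 ± 0.06, adjusted p = 0.00847) and RNF175 (0.27) rose, and PDZK1IP1 (-0.35) and the membrane protease gene ST14 (-0.28 ± 0.03, adjusted p = 0.00163) fell. Cholesterol synthesis genes fell as a list in that group, with 0 of 14 called and 9 lower when adjusted over the list alone (camera adjusted p = 2.09e-16, adjusted p = 0.0329 with an estimated correlation). Averaged over the 4 groups, the transcription factor PRDM1 (0.36 ± 0.05, adjusted p = 0.0117), LCE3D (0.34), CD68 (0.33 ± 0.04, adjusted p = 0.00367), ATP2C2 (0.33), SPINK7 (0.32) and CEACAM6 (0.31) rose, and FGFBP1 (-0.41), SERPINA3 (-0.33), ODC1 (-0.25), SAA1 (-0.24) and OXCT1 (-0.24) fell. Cholesterol synthesis genes fell in 7 of 14, with HMGCS1 at -0.27 ± 0.05, DHCR7 at -0.16 and LSS at -0.12, and in 12 when adjusted over the list alone (camera adjusted p = 1.11e-14, adjusted p = 0.0556 with an estimated correlation). EGF changed the slope of squamous genes, lower with EGF in 4 of 23 and in 14 when adjusted over the list alone, SERPINB3 at -0.49 ± 0.07 per day, SPRR1A at -0.52, SPRR3 at -0.65 and IVL at -0.62 (camera adjusted p = 1.71e-30, adjusted p = 0.0307 with an estimated correlation). Without the library labelled MCF10A without EGF at day 3 6 were lower. KRT23 (-0.66) and LINC01559 (-0.56) were lower too, and VIM (0.34) and RNF175 (0.30) were higher.

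For the slope in MCF10A without EGF limma called 563 genes, 451 rising and 112 falling, and 346 without the library labelled MCF10A without EGF at day 3. Without this group's array at day 1.5, 7 or 9 it called 1413, 237 or 94, and without days 1.5, 3, 5, 7 and 9 it called 954, 143, 245, 200 and 67. Centring each array on its median gave 488 rising and 53 falling. For the slope averaged over groups it called 150 genes, 83 rising and 67 falling, or 75 and 28 with centring, and 231 without that library. Single arrays left out, other than that one, moved this count to between 7 and 907 except for MCF10A without EGF at day 5 and MCF10A-HER2 with EGF at day 3, and left-out days to 2 (day 1.5), 9 (day 3), 11 (day 5), 13 (day 7) and 1035 (day 9).

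In MCF10A with EGF limma called 2 slopes, against 369 at an unadjusted p under 0.05, and 3 without the library labelled MCF10A without EGF at day 3. It called 1 without the group's array at day 1.5 or 3. In MCF10A-HER2 without EGF it called 0, against 310 unadjusted, and 2 without that library. In MCF10A-HER2 with EGF it called 4, 2 rising and 2 falling, and 17 without that library, 1 without the group's array at day 1.5, 7 without its array at day 7, 0 without its array at day 9, and 7 without MCF10A with EGF at day 7 or 9. EGF changed the slopes of 21 genes, 2 upward and 19 downward, and of 51 without that library. That count was 126 without MCF10A without EGF at day 1.5, 6 without MCF10A with EGF at day 1.5, 2 and 11 without MCF10A-HER2 without EGF at days 1.5 and 9, and 9 without MCF10A-HER2 with EGF at day 9. HER2 changed the slopes of 0 genes, against 439 unadjusted, of 1 without that library, and of 4 and 1 without MCF10A without EGF at days 1.5 and 5. Whole days left out in the order 1.5, 3, 5, 7 and 9 gave 0, 0, 1, 9 and 16 slopes in MCF10A-HER2 with EGF, and 0, 10, 4, 0 and 4 changed by EGF. In MCF10A with EGF 1 slope was called without day 1.5 or 5 and 0 without day 3 or 9, and HER2 changed 1 slope without day 5.

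Genes were also ordered along the chromosomes, because neighbours moved together between the lines. With the library labelled MCF10A without EGF at day 3 left out, 13 of 292 runs of 25 genes were higher and 22 lower in MCF10A-HER2 without EGF, and 13 and 30 with EGF. In both states 22 runs were lower and 10 higher. On chromosome 1, 13 of 30 runs, between PDE4DIP and TOMM20, were lower in both, with a median log2 change of -0.73 in each. On chromosome 5, 6 of 14 runs were lower, on chromosome 13, 3 of 4, and on chromosome 3, 9 of 17, between SLMAP and RPL35A, were higher. EGF in MCF10A-HER2 gave 0 such runs, and EGF in MCF10A gave 2 higher and 1 lower.

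**Figure D4:**
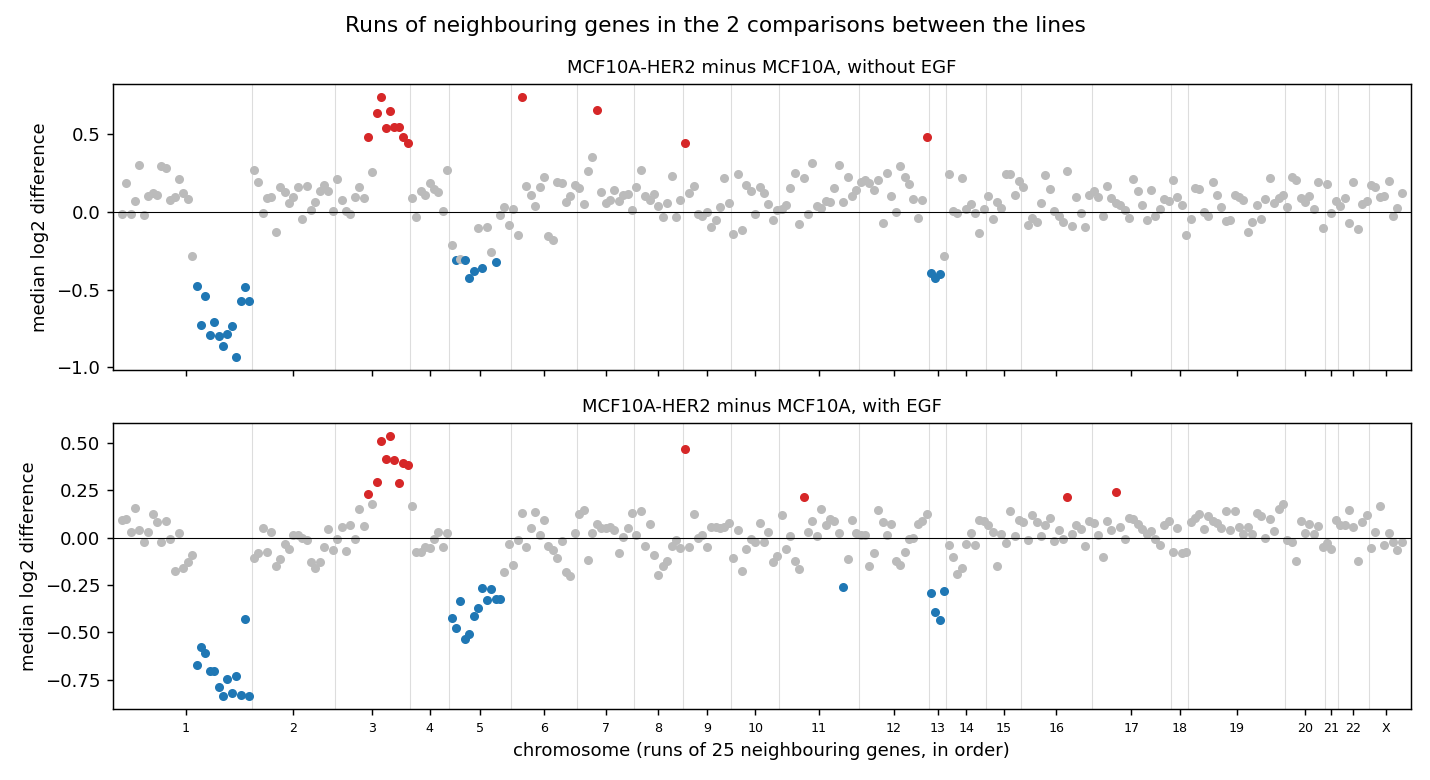
Median log2 change of runs of 25 neighbouring genes (vertical axes) in order along the chromosomes (horizontal axis) for the HER2 effect without and with EGF, fitted without the library labelled MCF10A without EGF at day 3. Each point is 1 run, red where called higher, blue where called lower and grey where not called, and 13 of the 30 runs of chromosome 1 are blue in both panels.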

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

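The tests of the line, of an exchange and of EGF in MCF10A cells as the cause in the library labelled MCF10A without EGF at day 3, and of a copy number difference, were chosen after the result was seen, and so was the reading of the marker test of 4 arrays. The orders of days for the slopes were drawn a second time after a first draw, which had counted a reversed order as a mirror image, had been seen, and no slope result changed sides of 1 in 20.

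In the library labelled MCF10A without EGF at day 3, ERBB2 was at 11.35. The median level of the genes in the 22 runs that are lower in MCF10A-HER2, defined without this library, was -0.195, at the edge of the range of the 10 arrays of MCF10A-HER2 (-0.312 to -0.195) and outside that of the other 9 arrays of MCF10A (0.161 to 0.399). The distance of 0.356 from the MCF10A range argues against induction of ERBB2 in MCF10A cells, and 0 arrays of MCF10A-HER2 had both values in the MCF10A range, which argues against an exchange within these 20 arrays. RNA of the MCF10A-HER2 line under this label is a candidate explanation, and on the 719 genes changed by EGF in that line the library lay at 0.582, above the arrays of that line without EGF (-0.054 to 0.066) and below those with EGF (0.719 to 1.246), so EGF in its culture may have added to it. The MCF10A arrays with EGF lay at 0.562 to 0.846 there, a range that holds this library, and its nearest array was MCF10A with EGF at day 1.5 (r = 0.983, against 0.947 for the nearest of its own group). EGF in a culture of MCF10A cells is argued against as the cause of the ERBB2 value, which lay 5.38 above the highest of the MCF10A arrays with EGF (5.65 to 5.97). An error of label, an exchange with a culture outside these arrays and a mixture of RNA stay open.

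Neighbouring genes shifted together between the lines, in 22 lower and 10 higher runs found both without and with EGF. Medians of runs had an r of 0.81 across runs between the 2 HER2 effects, which share no array, and 91.2% of 875 genes kept the sign of their run, as a copy number difference between the 2 lines would give. Of 35 runs called without EGF, 33 stayed called with the composition index as a covariate, which argues against a GC-related bias of the arrays as the whole cause. A copy number difference may explain these runs, but DNA was not measured here. Changes of chromatin over long stretches were not tested.

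On the second principal component, with 17.1% of the variance, the 4 highest arrays were taken as apart, with no test of a gap. They were MCF10A-HER2 with EGF at days 7 (25.88) and 9 (52.96), MCF10A-HER2 without EGF at day 7 (34.32) and MCF10A without EGF at day 7 (25.68). The next was at 16.89. At the other end MCF10A without EGF at days 1.5 and 5 lay at -37.06 and -37.23, further from 0 than 3 of the 4. Of the 4, 3 were among the 4 highest on the composition index. A GC-related technical bias was said to need 4, and 2 would have excluded it. Markers of other cell types differed from the other arrays of the groups by a median of 0.065, under the 0.2 set beforehand to exclude cells of another type. That bound was wrong, because the list mixes 4 kinds of cell and 6 of its 17 markers were lower, so a median cannot see 1 kind: CD68 was higher by 1.72 at a mean level of 7.65 and DCN by 0.43, while CD14 (-0.55), FAP (-0.59) and FABP4 (-0.26) were lower. Neither can be told apart from a change late in culture, since 3 of the 4 arrays are from day 7 and 1 from day 9, and epithelial cells also express CD68.

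Single arrays stood far from the other 4 of their group in 12 of 104 groups of values, where chance singles out about 1 in 20. They were ERBB2 in MCF10A-HER2 without EGF at day 7 (12.04, nearest other 11.57), EGFR in MCF10A-HER2 with EGF at day 9 (9.21, nearest 8.26) and the array median of MCF10A with EGF at day 5 (3.91, nearest 3.58). The library labelled MCF10A without EGF at day 3 stood apart in the mean of 4 lists, DNA replication (1.46), quiescence (-0.69), NF-kB (0.30) and the unfolded protein response (0.65). Other list means far from their group were mitosis in MCF10A-HER2 without EGF at day 7 (-0.43), quiescence in MCF10A-HER2 with EGF at day 1.5 (-0.66), the BCL2 family in MCF10A with EGF at day 5 (0.18), hemidesmosome genes in MCF10A without EGF at day 7 (-0.20) and YAP targets in MCF10A-HER2 without EGF at day 1.5 (-0.10).

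The EGF effect differed between the lines, by the interaction test, for IL1R2 (-2.24) and MYEOV (-2.05). Lists that differed by camera at the preset correlation had medians of -0.87 (DNA replication), -1.59 (mitosis), -0.34 (hemidesmosome, adjusted p = 0.0421), 0.12 (interferon, adjusted p = 0.00599), -0.27 (NF-kB, adjusted p = 0.0301), -0.49 (hypoxia, adjusted p = 0.00321), 0.28 (unfolded protein response, adjusted p = 0.00599), -0.69 (ribosome biogenesis, adjusted p = 1.36e-05) and -0.26 (oxidative phosphorylation, adjusted p = 0.0421). With an estimated correlation their adjusted p were 0.536 to 0.679. With the library labelled MCF10A without EGF at day 3 left out, hemidesmosome, interferon, unfolded protein response and oxidative phosphorylation no longer passed (adjusted p = 0.183, 0.0963, 0.242 and 0.105). EGF changed the slope on day of 21 genes. Among 12083 probe sets without a gene name, which the comparisons of genes did not use, limma called 121 (EGF in MCF10A), 11 (EGF in MCF10A-HER2), 31 (HER2 without EGF), 58 (HER2 with EGF), 1 (interaction) and 104 (HER2 against EGF), or 540, 43, 366, 102, 22 and 160 without the library labelled MCF10A without EGF at day 3. Their median log2 level was 2.39, against 4.39 for the 21214 named probe sets.

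Other splits of the arrays showed where chance can be excluded at 1 in 20. For comparisons of 2 groups they were drawn without regard to day, which the model takes as a block. For EGF in MCF10A-HER2 (356 genes) and for HER2 against EGF (1091), 1 of 100 splits, the real one, gave as many genes. The highest other gave 1, so chance is excluded for both, but only against splits that ignore day. Against such splits it is also excluded for HER2 with EGF (539), with 2 of 100 and a highest other of 584. That other split exchanged MCF10A with EGF at day 5 and MCF10A-HER2 with EGF at day 7. For EGF in MCF10A (1183) 5 of 100 gave as many, up to 3098, and for HER2 without EGF (522) 6 of 100, up to 1743, so chance is not excluded there. All the other splits with as many, 4 and 5, moved the library labelled MCF10A without EGF at day 3 to the other group, which points to a structure of the samples. Among 13 other splits that exchange arrays within days, the highest counts were 2532 and 1652 for these effects and 0 for EGF in MCF10A-HER2, HER2 with EGF and HER2 against EGF. So few cannot reach 1 in 20, so exchanges within days exclude chance for none of these comparisons. For the interaction (2) 3 of 100 gave as many, up to 135. These splits exchanged EGF labels within each line and so also broke up the EGF effects themselves. They cannot exclude chance for a difference between those effects. The splits that called many more genes again point to a structure of the samples.

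For the slopes the days were exchanged. For the slope averaged over groups (150), 1 of 100 gave as many, with a highest other of 37. The orders were drawn separately in each group, and so also broke up deviations that arrays of the same day share. The mean r of these deviations ran from -0.036 (day 9) to 0.345 (day 1.5), against -0.041 between days. Chance is therefore excluded there only against orders that ignore this sharing, and not for a course common to the 5 days. For MCF10A-HER2 with EGF (4) chance is excluded, with 2 of 100 and a highest other of 4. Chance is not excluded for MCF10A without EGF (563), with 14 of 100 and up to 3409, for MCF10A with EGF (2), with 6 and up to 3, or for the EGF effect on slope (21), with 11 and up to 942. For MCF10A-HER2 without EGF and the HER2 effect on slope 0 genes were called. All 100 then necessarily gave as many, up to 1 and 587, which decides nothing about chance. Orders and exchanges that called several times the real count point to a structure of the samples.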

How the results depend on the processing

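The fits without the 4 arrays taken as apart on the second component, those with the composition index, and the lists, overlap and ERBB2 level with arrays or days left out were chosen after the data were seen.

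With 1 array or day left out, counts ranged from 231 to 3421 (EGF in MCF10A), 80 to 719 (EGF in MCF10A-HER2), 1 to 2758 (HER2 without EGF), 152 to 924 (HER2 with EGF), 0 to 525 (interaction) and 599 to 1503 (HER2 against EGF). The highest of each came without the library labelled MCF10A without EGF at day 3. The lowest came without day 5, 9, 5, 1.5 and 5, and for the interaction without any of most arrays. Slopes ranged from 67 (without day 9) to 1413 (without day 1.5 of that group) in MCF10A without EGF, 0 to 3 in MCF10A with EGF, 0 to 2 in MCF10A-HER2 without EGF and 0 to 17 in MCF10A-HER2 with EGF. They ranged from 2 (without day 1.5) to 1035 (without day 9) averaged over groups, 0 to 126 for the EGF effect and 0 to 4 for the HER2 effect. ERBB2 differed by 3.07 to 4.34 without EGF and 5.91 to 6.04 with EGF. The overlap of the EGF and HER2 effects had an r of 0.508 (without MCF10A without EGF at day 9) to 0.75 (without the library labelled MCF10A without EGF at day 3). Without that library 13, 8, 9, 7, 8 and 5 lists passed in the 6 comparisons, against 12, 9, 11, 4, 9 and 4.

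The day block was tested by leaving it out, which gave 209 genes (EGF in MCF10A-HER2), 225 (HER2 without EGF), 355 (HER2 with EGF) and 1 (interaction). Arrays of the same day had a mean r of deviations of 0.345 (day 1.5), 0.312 (day 3), 0.115 (day 5), 0.28 (day 7) and -0.036 (day 9), against -0.041 between days, and the consensus correlation within a day was 0.0911. With day as a random block every count stayed within 1.5 times. With only the 2 groups in the fit the counts were 98 (EGF in MCF10A), 1 (HER2 without EGF), 1278 (HER2 with EGF) and 1856 (HER2 against EGF). The spread is estimated from fewer arrays there. The first 2 counts fell, from 1183 and 522, and those fits hold MCF10A without EGF. Arrays of that group had a mean r with the rest of their group of 0.915 to 0.960. In the other groups it was 0.966 to 0.986. With all 20 arrays these 2 comparisons are tested against a spread shared with those groups. The last 2 counts rose, and those fits hold no array of MCF10A without EGF. With the 4 groups but without the library labelled MCF10A without EGF at day 3 they were 924 and 1503. The causes of the fall and of the rise were not tested. The interaction has no such fit.

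Every probe set as its own feature gave 325 (HER2 without EGF), 76 (average slope) and 11 (EGF on slope), with more features tested. The dimmer 50% of genes left out gave 1 (interaction), 0 (slope in MCF10A with EGF), 2 (slope in MCF10A-HER2 with EGF) and 5 lists (EGF in MCF10A-HER2). A second quantile normalisation gave 1 (slope in MCF10A with EGF), and centring on the median gave 0 (interaction), 4 (slope in MCF10A with EGF) and 32 (EGF on slope). Trend and robust variance gave 33 (EGF on slope). Day as log2 gave 146 (slope in MCF10A without EGF), 0 (slope in MCF10A with EGF) and 2 (EGF on slope). The 1.5-fold minimum, the rank of day and the mean of probe sets moved no count beyond 1.5 times. For the shifts named without a reason the cause was not tested.

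Without the 4 arrays apart the counts were 458 (EGF in MCF10A), 17 (EGF in MCF10A-HER2), 2 (HER2 without EGF), 106 (HER2 with EGF) and 0 (interaction), and slopes 225 (MCF10A without EGF), 1 (MCF10A with EGF), 0 (MCF10A-HER2 with EGF), 0 (average) and 0 (EGF on slope). With the library labelled MCF10A without EGF at day 3 left out too they were 2926 (EGF in MCF10A), 2399 (HER2 without EGF) and 360 (interaction), and slopes 361, 4, 3 and 0 (the 4 groups in order), 4 (average) and 1 (EGF on slope). Both have fewer arrays. The composition index gave 651 (EGF in MCF10A-HER2), 990 (HER2 without EGF), 0 (interaction), 269 (slope in MCF10A without EGF), 13 (slope in MCF10A-HER2 with EGF), 83 (average slope), 38 (EGF on slope) and 1 (HER2 on slope). The cause was not tested.

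With all arrays, an estimated correlation in camera left 0 lists in each of the 6 comparisons. It left, in the fit without the library labelled MCF10A without EGF at day 3, NF-kB genes for EGF in each line and NRF2 genes for EGF in MCF10A-HER2 (adjusted p = 0.0391, 0.0394 and 0.0394). Rank-based camera left 2 (HER2 against EGF), and leaving out day 1.5 gave 8 (HER2 with EGF) and 9 (HER2 against EGF). Split controls gave an overlap of 0.286, where the shared arrays are removed and each effect also rests on fewer days. ERBB2 has 1 probe set, so another could not be tried.

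Of 148 results for named genes 50 had the same direction and side of the threshold in all settings, and 1 changed sign, the EGF effect on ERBB2 in MCF10A-HER2, never called, which ranged from -0.10 (without MCF10A-HER2 without EGF at day 3) to 0.49 (without MCF10A-HER2 with EGF at day 3) and was -0.02 without MCF10A-HER2 with EGF at day 1.5. With arrays or days left out 600 values lost their call and 3 gained one, against 3095 with neither. Calls were lost by 82 without the 4 arrays apart, 35 with only the groups, 25 without those 4 arrays and the library labelled MCF10A without EGF at day 3, 21 with every probe set, 13 with the composition index, 9 with centring, 9 without the day block, 6 with quantile normalisation and 2 with the random block. No background level of the arrays was used here, so small changes of dim genes are limited by the signal of their probe sets.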

Other observations

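No test in this part was planned, and its values were picked after they were seen. FABP4 in MCF10A-HER2 without EGF had log2 values of 5.08, 7.30, 9.15, 8.56 and 9.40 at days 1.5, 3, 5, 7 and 9, against 1.40 to 2.96 with EGF. CCNB1 in MCF10A without EGF was at 7.42 at day 1.5 and at 4.88, 3.38 and 4.15 at days 5, 7 and 9, and at 9.29 in the library labelled MCF10A without EGF at day 3. DUSP6 lay at 6.42 to 7.42 in MCF10A-HER2 without EGF, between MCF10A without EGF (2.98 to 4.33, and 8.33 in that library) and MCF10A with EGF (8.77 to 9.52).

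Cholesterol synthesis genes had falling slopes as a list in MCF10A-HER2 without EGF too (camera adjusted p = 1.24e-11, adjusted p = 0.109 with an estimated correlation), with 0 of 14 genes called there by limma. Squamous genes had rising slopes as a list in that group (camera adjusted p = 4.76e-09, adjusted p = 0.273 with an estimated correlation), with 0 of 23 called and 3 when adjusted over the list alone, and falling ones in MCF10A-HER2 with EGF (camera adjusted p = 4.5e-09, adjusted p = 0.181 with an estimated correlation), with 0 called and 6 when adjusted over the list alone, or 3 called without the library labelled MCF10A without EGF at day 3.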
